A study of Mus musculus with 8 samples.

How the data were processed

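Gene expression was measured in 8 samples of mouse pro-B cells, the precursors that rearrange the immunoglobulin heavy chain genes in bone marrow. Each sample was hybridised to 1 Affymetrix gene array. Per the labels, the samples form 4 groups of 2: cells from bone marrow with an intact or a deleted Setdb1 gene and no Bcl2 transgene, and Bcl2-transgenic cells with an intact or a deleted Setdb1 gene that were kept in interleukin-7 for 4 days. Culture and the Bcl2 transgene therefore always went together. Setdb1 encodes a histone methyltransferase that places methyl groups on lysine 9 of histone H3. Per the labels' protocols, pro-B cells were purified by fluorescence-activated sorting, RNA was isolated on columns, amplified with Nugen Ovation kits and labelled with biotin. A growth protocol given for every sample describes the culture step also for the bone marrow samples, while the series' design text says that these cells came directly from the marrow. The groups were taken from the sample labels. Nothing in the labels says that the 2 samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 2 per group, limits the precision of every value.

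The deposited table holds log2 values for 241576 probesets, 8 columns, with no missing value. Per the submitters' processing notes, these log2 values were made with Affymetrix Expression Console 1.2.0.20 and RMA (robust multi-array averaging: background correction, quantile normalisation and summary of probes). They were used as deposited. A probeset here covers a part of a gene. The platform annotation named 1 gene symbol for 212097 probesets, several for 4475 and none for 25004. Probesets with several symbols were not used, and probesets without a symbol were examined apart from the genes. Of the array's symbols, 17621 are current in the RefSeq gene table of assembly GRCm38.p6, 2742 were matched through a synonym and 53 had no match. That table was used for names and for the order of genes only, so no coordinates are given. Array symbols are printed as the array gives them.

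The value of a gene in an array was computed as the median polish over its probesets (median 8 probesets per gene, 1 probeset for 2292 of 20416 genes). Genes entered the tests when their value lay above the 25th percentile of all gene values, a log2 value of 4.03, in at least 2 arrays. This left 16050 genes, and 4366 were left out as dim. One linear model with 4 group means was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the variances (4 residual and 3.53 prior degrees of freedom). Version 1.17.8 of data.table read the files. All tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The contrasts were deletion in bone marrow, deletion in culture, the difference between these effects (the interaction), their mean, and culture against bone marrow in control cells. Changes are log2 differences with the standard error (SE) of the moderated fit.

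Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 27 lists within a contrast. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move one way. Lists with under 5 tested members were not to be tested, and none was that short. The lists were heterochromatin machinery, germline genes, imprinted genes, clustered protocadherins, interferon response, viral sensing and restriction, unfolded protein response, p53 targets, BCL2 family, early B-lineage genes, pre-B and mature B genes, IL-7 and STAT5 targets, DNA replication, mitosis, immediate early and heat shock, cholesterol synthesis, and glycolysis and hypoxia. Markers of other cells were listed for neutrophil and monocyte, erythroid, T cell, NK and innate lymphoid, plasmacytoid and conventional dendritic, megakaryocyte, mast cell and basophil, stem and progenitor, plasma cell, and stromal and endothelial. Some genes stand on more than 1 list, such as Xbp1. Members were also adjusted over the list alone.

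The lists, the groups, the tests and the rule for the genes named were fixed before the data were examined. The rule takes Setdb1 with its probesets. For each deletion contrast and the culture contrast it takes the 10 largest rises and the 10 largest falls past 0.05, among genes with at least 3 probesets whose arrays of 1 group all lie above those of the other. With 2 arrays against 2, chance alone separates 33.33% of genes in this way. It also takes up to 4 members of each list past 0.05 per deletion contrast, or up to 2 with the lowest p, given as values, where none passes. For the interaction it takes the 5 largest in each direction past 0.05. Any other gene named was chosen after its values were seen.

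The model was tested on simulated data for deletion in culture, with 200 genes changed among 16447. It called 11% of genes changed 2-fold, 90% of genes changed 4-fold and 3 unchanged genes. The changed genes were drawn from genes above the median value with at least 3 probesets. Noise was alike in all groups and independent between genes. The data also hold dimmer genes and groups of unequal spread, so these values need not hold there. Alternatives covered the filter, the summary of probesets, scaling between arrays, the variance model, the arrays in the fit, the threshold, a replicate block, the list test, and leaving out each array. Further alternatives, chosen after seeing the data, were the mean of the neutrophil and monocyte markers as a covariate, leaving out both culture arrays numbered 2, and the lists in the interaction and in the mean of both effects. Changes between probesets of 1 gene were tested with limma's diffSplice. Every array column of the table was used.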

Results

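The study asked which genes depend on Setdb1, a histone H3 lysine 9 methyltransferase, in mouse pro-B cells, and its title places this in the control of retroviruses. RNA was measured on 8 arrays: 2 of control and 2 of Setdb1-deleted cells from bone marrow, and 2 of control and 2 of deleted Bcl2-transgenic cells after 4 days in interleukin-7 (IL-7). IL-7 is the cytokine that sustains pro-B cells in culture, and the Bcl2 transgene protects cells from apoptosis. The median gene value of the arrays lay between 5.25 and 5.33 on the log2 scale.

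Replicates correlated over genes at r = 0.945 in bone marrow controls, 0.988 in deleted bone marrow cells, 0.971 in culture controls and 0.968 in deleted cultured cells. The first principal component held 33.0% of the variance and the second 24.0%. On the second, the 4 control arrays had scores from 16.1 to 29.1 and the 4 deleted arrays from -29.1 to -17.8. Bone marrow control 1 stood apart on the first component, at -50.5 against -10.9 for bone marrow control 2. The neutrophil and monocyte list differed by a mean of 0.15 between these arrays, with members on both sides. Csf1r (10.18), Emr1 (10.03) and Cd68 (11.07) read higher in control 1 than in control 2 (7.86, 6.65 and 8.26), and Mpo (9.60 against 11.19) and Ctsg (6.82 against 8.87) read lower. In culture, S100a8 of the same list was at 5.68 and 7.83 in control and deleted culture 1, and at 11.80 and 11.92 in control and deleted culture 2. These genes were chosen after their values were seen.

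**Figure D1:**
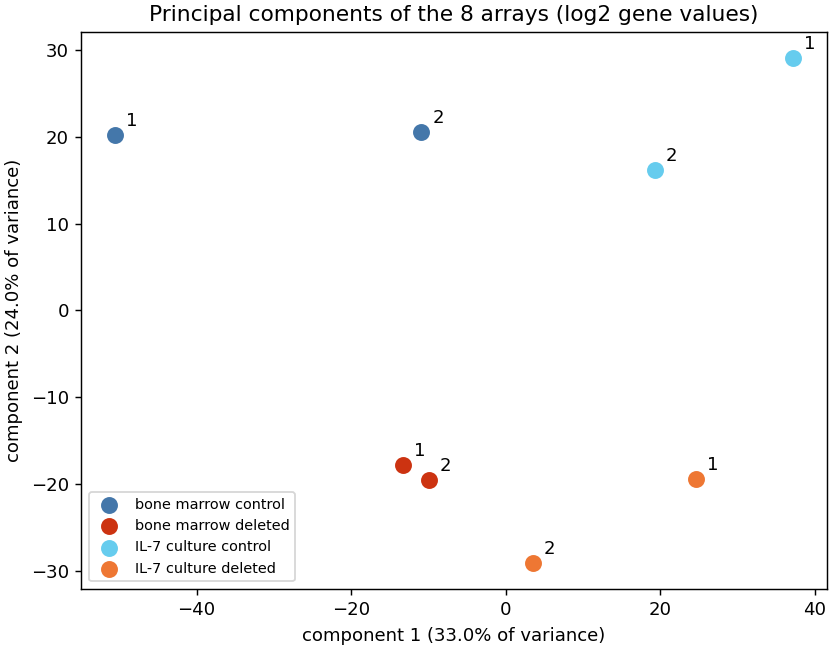
Principal components 1 and 2 of the log2 gene values, 1 point per array, numbered by replicate. Component 2 places all 4 deleted arrays below 0 and all 4 control arrays above 0, and bone marrow control 1 lies farthest left, at -50.5 on component 1.

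Setdb1 itself was read by 23 probesets. Its gene value was 7.02 and 6.67 in the bone marrow controls, 6.74 and 6.53 in the deleted bone marrow cells, 6.84 and 6.45 in the culture controls, and 6.66 and 6.99 in the deleted cultured cells. The change over both conditions was -0.01 (SE 0.15, adjusted p = 0.973). With limma, 0 of the 23 probesets passed the threshold over these probesets in either condition, against 1 in bone marrow, which was lower, and 3 in culture, which were higher, at an unadjusted p under 0.05. In bone marrow, 7 probesets read lower and 2 higher in both deleted arrays than in both controls, and in culture 2 read lower and 7 higher, where chance separates 33.33% in either direction. The sources used here do not say which part of the gene was deleted, and probesets outside that part check nothing, so these values do not test the labels.

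In bone marrow pro-B cells with Setdb1 deleted, Cd74, the invariant chain of MHC class II molecules, fell by 3.23 on the log2 scale (SE 0.20, n = 2 per group, adjusted p = 0.00368). The class II chain H2-Aa fell by 2.79 (SE 0.20) and H2-Eb1 fell by 2.91 (SE 0.30). Cd55, a surface inhibitor of complement, fell by 2.76 (SE 0.17), and Bank1, a scaffold of B-cell receptor signalling, fell by 3.45 (SE 0.30, adjusted p = 0.0181). Lalba, the milk protein alpha-lactalbumin, rose from 4.07 ± 0.68 to 7.48 ± 0.30 (SD, n = 2), a change of 3.41 (SE 0.32, adjusted p = 0.023). Lalba in bone marrow control 1 (3.59) and Bank1 in deleted array 1 (3.84) lay under 4.03, the value set for dim genes, so the sizes of these changes are uncertain.

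Members of the neutrophil and monocyte list stood on both sides in the same arrays. Csf1r read -2.20 (SE 0.75, adjusted p = 0.327), Emr1 -2.65 (SE 0.97, adjusted p = 0.358) and Cd68 -2.50 (SE 0.94, adjusted p = 0.365) with deletion in bone marrow, and Ms4a3 read 1.86 (SE 0.45, adjusted p = 0.185) and Prtn3 1.88 (SE 0.63, adjusted p = 0.323). Like Csf1r, Emr1 and Cd68, Cd74 (11.08 against 10.79) and H2-Aa (10.59 against 10.27) read higher in bone marrow control 1 than in control 2. In culture, where Cd74 and H2-Aa also fell, Csf1r read 1.78 (SE 0.75, adjusted p = 0.321), Emr1 1.03 (SE 0.97) and Cd68 1.35 (SE 0.94). These list members were chosen after their values were seen.

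In bone marrow 6 genes rose and 15 fell in all, among the 16050 tested. The other rises were Clgn, a chaperone of the endoplasmic reticulum best known from testis (2.56, SE 0.27), Akap5 (from a mean of 5.17 to 7.18, SE of the change 0.18), the fatty acid desaturase Fads2 (1.92, SE 0.20), the cytokine signalling inhibitor Socs2 (1.79, SE 0.22) and Nlrc3 (1.19, SE 0.15). Scd1, another desaturase, fell by 3.95 (SE 0.46, adjusted p = 0.0345), the innate receptor Tlr1 fell by 2.99 (SE 0.33) and Pgap1 fell by 2.87 (SE 0.34). Aim1 fell by 1.49 (SE 0.17) and Arhgap17 fell by 1.41 (SE 0.16).

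The list of pre-B and mature B genes lay lower by a mean of -1.65 over 24 tested genes in bone marrow (camera adjusted p = 7.38e-20). With an estimated correlation the adjusted p was 0.423. Of its members 3 fell over all genes and 14 fell adjusted over the list alone, and bone marrow control 1 had a mean 0.85 lower than control 2. Among early B-lineage genes, which include the surrogate light chain and the recombinase, 1 of 32 fell over all genes, and 5 rose and 4 fell adjusted over the list alone (mean 0.09, adjusted p = 0.356, 0.36 with adjusted p = 0.00285 without bone marrow control 2, and -0.19 with adjusted p = 0.323 without bone marrow control 1). Genes of DNA replication were higher in 26 of 26 cases, by a mean of 0.51 (adjusted p = 5.19e-12, and 0.423 with an estimated correlation). With limma 0 of them passed over all genes (16 at an unadjusted p under 0.05) and 10 rose adjusted over the list alone, with Tyms at 1.09 (SE 0.18, adjusted p = 0.0824). Mitosis genes had a mean of 0.31 (adjusted p = 8.89e-06, and 0.425 with an estimated correlation), and 0 of 24 passed over all genes or over the list alone (5 at an unadjusted p under 0.05).

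Cholesterol synthesis genes had a mean of 0.44 (adjusted p = 1.14e-05, and 0.423 with an estimated correlation), with 0 of 16 past over all genes (9 at an unadjusted p under 0.05) and 7 risen adjusted over the list alone. Fdps read 0.87 (SE 0.14) and Hmgcs1 0.87 (SE 0.17). The unfolded protein response, the reaction to misfolded protein in the endoplasmic reticulum, had a mean of 0.37 (adjusted p = 1.63e-05, and 0.423 with an estimated correlation), with 0 of 32 past (17 unadjusted) and 7 risen adjusted over the list alone. Heterochromatin machinery had a mean of 0.23 (adjusted p = 0.00211, and 0.423 with an estimated correlation), with 0 of 28 past over all genes or adjusted over the list alone (8 unadjusted) and Trim28 at 0.58 (SE 0.14). Interferon response genes had a mean of -0.48 (adjusted p = 3.23e-06, and 0.425 with an estimated correlation), with 0 of 39 past (11 unadjusted), 1 fallen adjusted over the list alone, and Oas1g at -1.35 (SE 0.25). In bone marrow control 1 this list lay 0.26 above control 2.

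Mast cell and basophil markers had a mean of -0.76 (adjusted p = 1.15e-05, and 0.423 with an estimated correlation), with 0 of 9 past (7 unadjusted) and 1 risen and 5 fallen adjusted over the list alone, with Mcpt8 at -2.03 (SE 0.31). Without bone marrow control 2 this mean was -0.27 (adjusted p = 0.332). Immediate early and heat shock genes had a mean of -0.37 (adjusted p = 0.0017, and 0.423 with an estimated correlation), with 0 of 18 past (6 unadjusted) and 1 fallen adjusted over the list alone. Without bone marrow control 1 their mean was -0.09 (adjusted p = 0.26). The count of 21 genes depended on single arrays. With limma it was 0 without deleted array 1 or 2 of bone marrow (1183 and 942 at an unadjusted p under 0.05), 9 without control 1 and 531 without control 2, and 3 and 2 without deleted culture 1 and 2.

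In IL-7 cultured cells with Setdb1 deleted, Faim3, the receptor for immunoglobulin M now called Fcmr, fell by 3.86 (SE 0.65, n = 2 per group, adjusted p = 0.0395), and Cd55 fell by 3.82 (SE 0.17, adjusted p = 0.000663). The inhibitory receptor Btla fell by 3.08 (SE 0.55). Thy1, a surface protein of T cells and several other cells, rose by 3.29 (SE 0.39), and Prkcq, a kinase of T-cell receptor signalling, rose by 2.64 (SE 0.22, adjusted p = 0.00982). Pdia6 and Hyou1, chaperones of the endoplasmic reticulum, rose by 1.36 (SE 0.15) and 1.45 (SE 0.21).

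Of 16050 genes 118 rose and 114 fell. Vmn2r96, a vomeronasal receptor gene, rose from 3.06 ± 0.80 to 7.66 ± 0.44 (SD, n = 2), a change of 4.59 (SE 0.45, adjusted p = 0.0117). Its control mean lay under 4.03, the value set for dim genes, so the size of this rise is uncertain. Gm5111, a predicted gene, rose by 3.80 (SE 0.31), Lalba by 3.37 (SE 0.32), the sialyltransferase St6galnac5 by 3.34 (SE 0.31), and Gldc, an enzyme of glycine breakdown, by 3.17 (SE 0.57). Sparc, a matrix protein, rose by 2.84 (SE 0.49), Gm6236 by 2.74 (SE 0.49) and the chemokine Ccl2 by 2.65 (SE 0.37). Gm6236 lay under the value for dim genes in control culture 1 (3.73). Among the largest falls, Ms4a4c fell by 3.37 (SE 0.51), Angptl1 fell by 3.12 (SE 0.41), Il4i1 fell by 2.92 (SE 0.28), Ralgps2 fell by 2.68 (SE 0.32), Cpm fell by 2.62 (SE 0.43), Zfp318 fell by 2.43 (SE 0.31) and Bank1 fell by 2.42 (SE 0.30).

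The unfolded protein response list rose by a mean of 0.73 over 32 genes (adjusted p = 8.42e-16, fry adjusted p = 0.00793), with an adjusted p = 0.153 under an estimated correlation. Over all genes 7 members rose, among them Asns (1.54, SE 0.24), which makes asparagine, and the transcription factor Xbp1 (1.43, SE 0.22), and 23 rose adjusted over the list alone. Pre-B and mature B genes had a mean of -1.60 (adjusted p = 4.95e-16, and 0.271 with an estimated correlation). Over all genes 6 of 24 fell, including Cd74 (-1.65, SE 0.20), H2-Aa (-1.62, SE 0.20), Cd22 (-2.02, SE 0.27) and Ciita, the regulator of class II genes (-1.87, SE 0.31), and 18 fell adjusted over the list alone. Early B-lineage genes had a mean of -0.32 (adjusted p = 0.00584, and 0.775 with an estimated correlation) and moved both ways. Vpreb2, part of the surrogate light chain, rose by 1.46 (SE 0.19) and Lef1 rose by 0.97 (SE 0.16), while Bank1 and Cd24a (-0.84, SE 0.14) fell, and 5 rose and 11 fell adjusted over the list alone. Without deleted culture 2 the mean of this list was -0.21 (adjusted p = 0.183), and without both culture arrays numbered 2 it was -0.20 (adjusted p = 0.223).

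Glycolysis and hypoxia genes had a mean of 0.52 (adjusted p = 3.15e-07, and 0.452 with an estimated correlation), with Pdk1 risen by 1.09 (SE 0.18) as 1 of 25 and 12 risen adjusted over the list alone. Cholesterol synthesis genes had a mean of 0.32 (adjusted p = 0.000951, and 0.452 with an estimated correlation), with Dhcr7 risen by 0.86 (SE 0.16) as 1 of 16 and 2 risen adjusted over the list alone. DNA replication genes had a mean of 0.23 (adjusted p = 0.00323, and 0.775 with an estimated correlation), with 0 of 26 past over all genes in limma (2 unadjusted) and 1 risen adjusted over the list alone. Without control culture 1 this mean was 0.11 (adjusted p = 0.29) without deleted culture 2 it was 0.13 (adjusted p = 0.251), and with the neutrophil and monocyte covariate it was 0.16 (adjusted p = 0.0563).

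Stromal and endothelial markers had a mean of 0.84 (adjusted p = 0.000138, and 0.153 with an estimated correlation), with Sparc risen as 1 of 12 and 3 risen adjusted over the list alone. T cell markers had a mean of 0.57 (adjusted p = 0.00584, and 0.271 with an estimated correlation), with Thy1 risen as 1 of 15 and 4 risen adjusted over the list alone. Without deleted culture 1 the mean was 0.64 with an adjusted p of 0.0726. Neutrophil and monocyte markers had a mean of 0.75 (adjusted p = 0.151), 1.98 (adjusted p = 0.000189) without control culture 2 and 1.78 (adjusted p = 0.002) without deleted culture 1. The mean turned to -0.44 (adjusted p = 0.66) without control culture 1 and to -0.25 (adjusted p = 0.84) without deleted culture 2, and was 0.97 (adjusted p = 0.000232) without both culture arrays numbered 2. In control and deleted cells array 2 lay above array 1 by 2.41 and 2.05. The count of 232 genes fell to 1 without deleted array 1 or 2 of bone marrow, 1 without control culture 1, 34 without control culture 2, and 6 and 4 without deleted culture 1 and 2. Without both culture arrays numbered 2, an alternative chosen after seeing the data, it was 5.

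**Figure D2:**
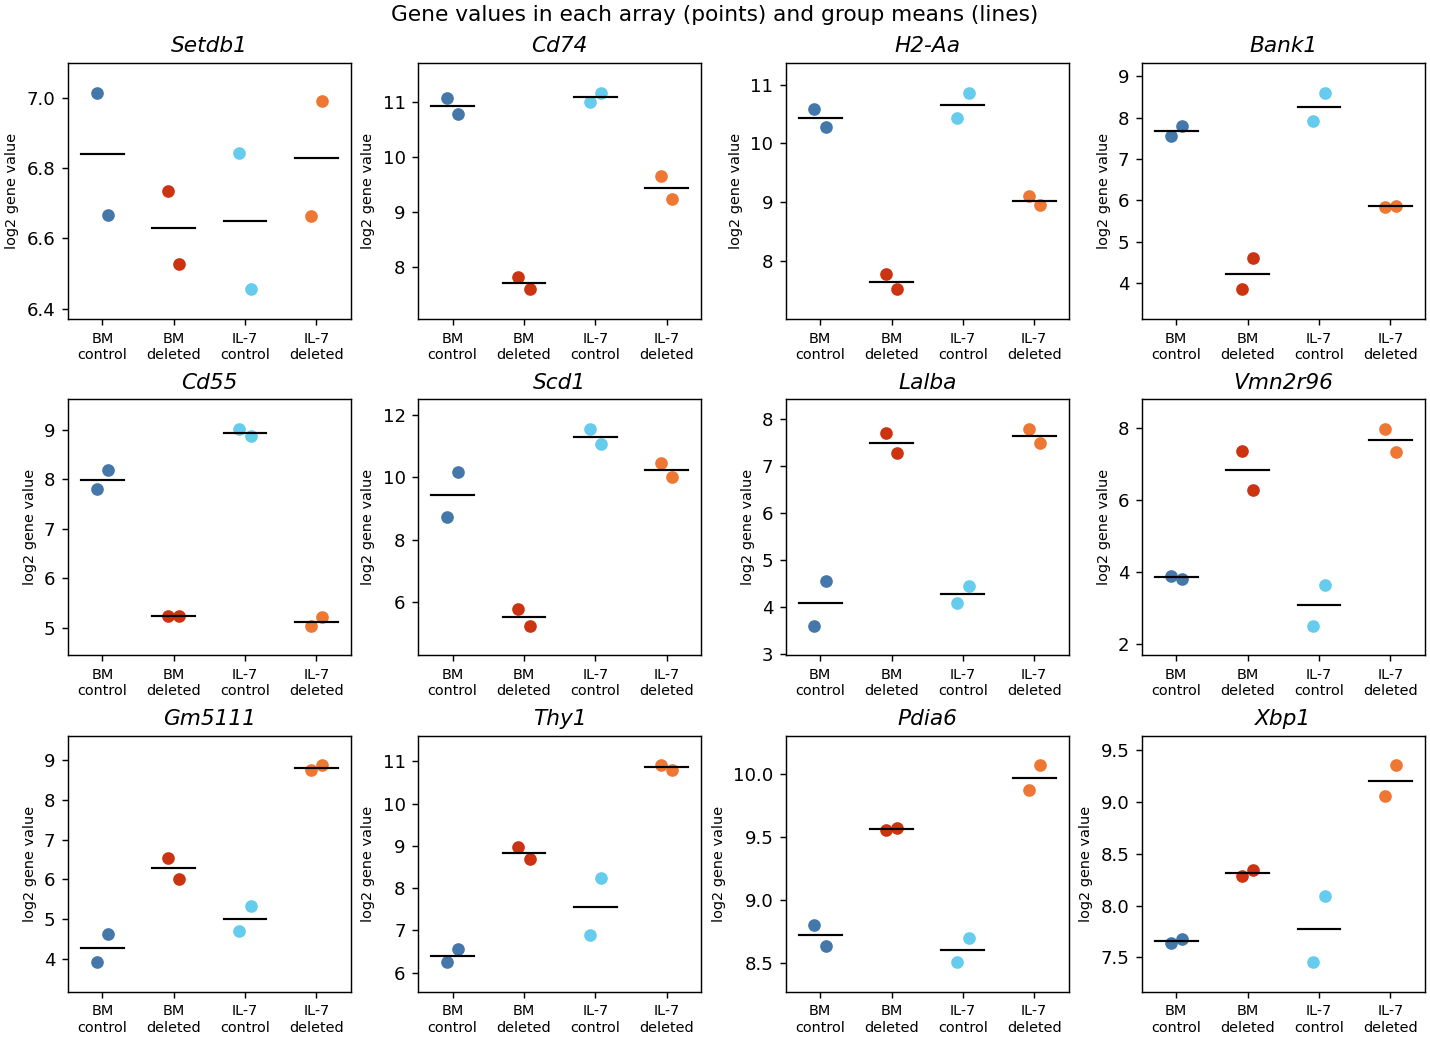
Log2 values of 12 genes in each array (points) with group means (lines), for bone marrow (BM) and IL-7 culture, control and deleted. Cd74, H2-Aa, Bank1 and Cd55 read lower and Lalba, Vmn2r96 and Thy1 higher in every deleted array than in the controls of the same condition, and Setdb1 overlaps between groups.

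Single members of other lists changed in culture. Cish, a target of STAT5 signalling, rose by 1.76 (SE 0.22), Slc7a1, the receptor of ecotropic retroviruses, rose by 1.12 (SE 0.16), and Samhd1, which depletes nucleotides needed by retroviruses, fell by 1.62 (SE 0.23). Rrm2b, a ribonucleotide reductase subunit induced by p53, fell by 1.54 (SE 0.28). Their lists did not pass in either deletion contrast: IL-7 and STAT5 targets had means of 0.18 and 0.01 in bone marrow and culture (adjusted p = 0.188 and 0.864), viral sensing and restriction -0.18 and -0.02 (0.188 and 0.963), and p53 targets -0.02 and -0.24 (0.551 and 0.188). In culture the test's direction was down for IL-7 and STAT5 targets and up for viral sensing and restriction, against the sign of each mean. Interferon response genes had a mean of 0.23 in culture (adjusted p = 0.384), with 0.0392 without control culture 1, 0.000463 without deleted culture 1, and -0.22 (adjusted p = 0.0326) without both culture arrays numbered 2. Mitosis genes had a mean of 0.12 (0.188, and 0.00687 without deleted culture 1), heterochromatin machinery 0.04 (0.738), and immediate early and heat shock -0.15 (0.188).

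Germline genes, imprinted genes and clustered protocadherins, which heterochromatin holds silent in many cells, did not pass at the settings fixed before the data were examined. Of the genes listed, 13 of 34 germline genes, 21 of 28 imprinted genes and 5 of 22 protocadherins were tested. The others were absent from the array or left out as dim, so these tests say nothing about them. The mean log2 value of the tested protocadherins lay between 4.09 and 4.41 in the arrays, close to the value set for dim genes. Germline genes had mean changes of 0.38 in bone marrow and 0.27 in culture (adjusted p = 0.0792 and 0.196). In bone marrow they passed without control 2 (0.46, adjusted p = 0.0159) and with the mean of probesets (0.36, adjusted p = 0.0398). Imprinted genes had means of 0.01 and 0.04 (0.859 and 0.801), with the test's direction down in both and the median at -0.06 in culture, and clustered protocadherins -0.12 and 0.16 (0.35 and 0.591). The meiotic cohesin gene Stag3 read 2.35 (SE 0.42, adjusted p = 0.111) in bone marrow and 2.04 (SE 0.42, adjusted p = 0.0708) in culture. H19 read 1.63 in culture (SE 0.41, adjusted p = 0.122). The BCL2 family had means of 0.21 and 0.03 (0.157 and 0.864), with Bcl2l11, which promotes apoptosis, at 1.09 (SE 0.33) and 1.71 (SE 0.33, adjusted p = 0.062).

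Markers of the remaining cell types also did not pass in bone marrow or culture at these settings. Their means were -0.13 and 0.09 for erythroid (adjusted p = 0.551 and 0.308), -0.14 and 0.23 for NK and innate lymphoid (0.398 and 0.188), -0.20 and 0.45 for plasmacytoid and conventional dendritic (0.118 and 0.0865), -0.14 and 0.34 for megakaryocyte (0.488 and 0.375), 0.31 and 0.24 for stem and progenitor (0.154 and 0.344), and -0.13 and 0.06 for plasma cell (0.922 and 0.903). Without bone marrow control 2 the bone marrow adjusted p was 0.0123 for stem and progenitor, and without deleted array 1 of bone marrow it was 0.0292. Dendritic markers in culture had an adjusted p of 0.007 without control culture 2, 0.0436 without deleted culture 1 and 0.0154 without both culture arrays numbered 2, and in bone marrow they passed with the mean of probesets (-0.29, adjusted p = 0.0326). In bone marrow the means were -0.43 for neutrophil and monocyte (0.456), whose members went both ways, 0.09 for T cell (0.918), 0.14 for stromal and endothelial (0.154) and 0.13 for glycolysis and hypoxia (0.16, and 0.0336 without bone marrow control 1). With the neutrophil and monocyte covariate the latter lists had an adjusted p of 0.0472 and 0.0428, and stromal and endothelial markers one of 0.0455 with a filter at the 50th percentile. The T cell test's direction in bone marrow was down with a median of -0.04, and the plasma cell median in culture was -0.35, with Xbp1 shared with the unfolded protein response list as its 1 risen member. Mast cell and basophil markers had a mean of -0.06 in culture (0.732).

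**Figure D3:**
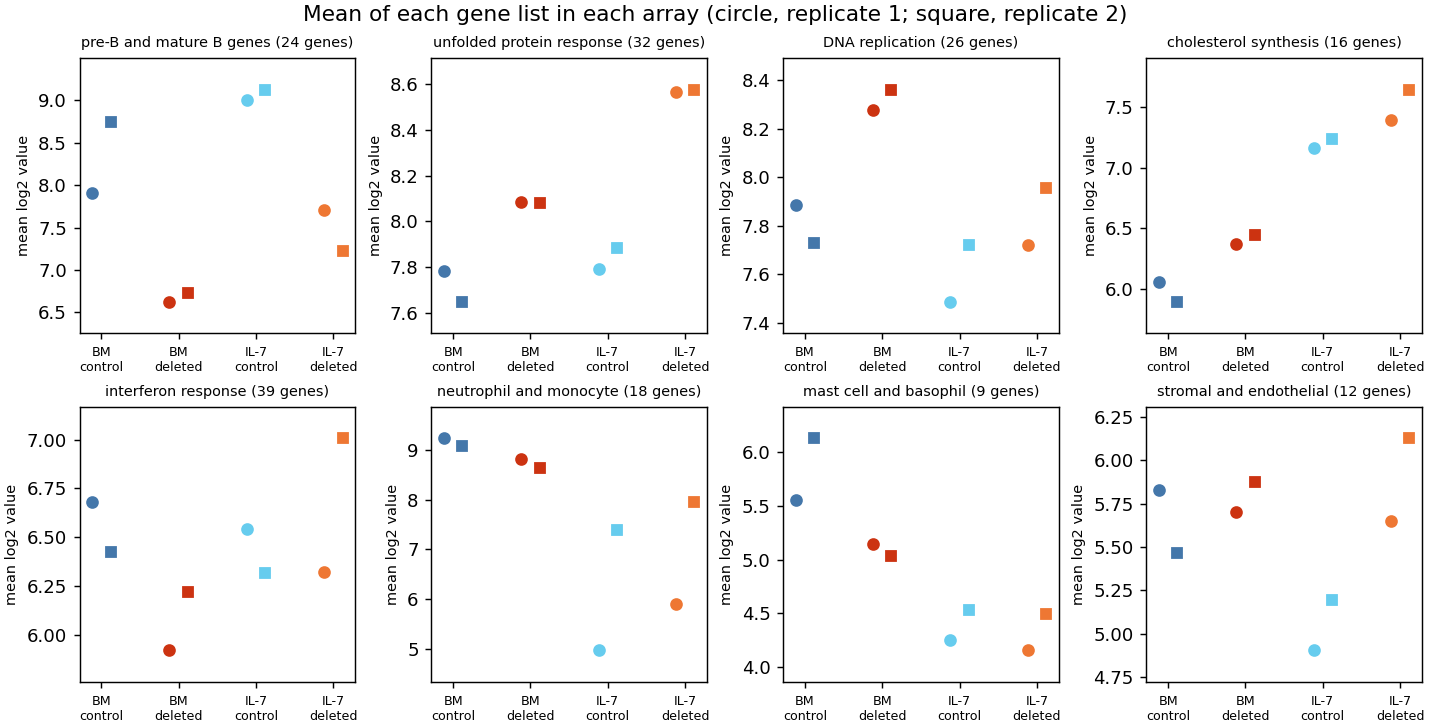
Mean log2 value of 8 gene lists in each array, circles for replicate 1 and squares for replicate 2, for bone marrow (BM) and IL-7 culture, control and deleted. Pre-B and mature B genes lie lower in every deleted array than in the controls of the same condition, and neutrophil and monocyte genes lie 2.41 and 2.05 higher in culture arrays numbered 2 than in arrays numbered 1.

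Across both conditions, taken as the mean of both effects, 238 genes rose and 221 fell. Pre-B and mature B genes fell in 16 of 24 cases over all genes and 20 adjusted over the list alone, where 1 rose, with a mean of -1.62 (adjusted p = 6.74e-21, and 0.227 with an estimated correlation). Ms4a1, which encodes CD20, fell by 4.22 (SE 0.51), and the immunoglobulin E receptor Fcer2a fell by 3.09 (SE 0.47). The means of Ms4a1 in deleted bone marrow cells (3.62) and of Fcer2a in deleted bone marrow (3.85) and cultured cells (3.99) lay under the value of 4.03 set for dim genes, so the sizes of these falls are uncertain. Among early B-lineage genes 5 rose and 5 fell: the surrogate light chain genes Vpreb2 (1.38, SE 0.14) and Igll1 (0.98, SE 0.16) and the transcription factor Erg (1.05, SE 0.19) rose, and Bach2 (-1.18, SE 0.21), Blk (-1.13, SE 0.17) and Cd72 (-1.35, SE 0.19) fell. The unfolded protein response had 13 of 32 members risen, and adjusted over the list alone 21 rose and 1 fell (mean 0.55, adjusted p = 1.02e-12, and 0.227 with an estimated correlation). Stag3 rose by 2.19 (SE 0.30, adjusted p = 0.0151) and Zcwpw1, a reader of histone marks in meiosis, rose by 0.82 (SE 0.14). Genes named for this mean outside the earlier contrasts were chosen after their values were seen. Its count of 459 was 13 and 14 without deleted array 1 and 2 of bone marrow, 46 and 146 without control culture 1 and 2, and 95 and 43 without deleted culture 1 and 2.

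Some genes passed both in bone marrow and in culture. Lalba, Akap5 and Fads2 rose in both. Cd74, H2-Aa, Bank1, Cd55, Aim1, Arhgap17, Rgs2 and Gm6545 fell in both. The values compared share no array, but both tests use 1 estimate of each gene's spread over all 8 arrays, so the calls are not independent and no p is given for these counts. Of the 21 genes called in bone marrow 20 had the same sign in culture, and of the 232 called in culture 212 had the same sign in bone marrow. Across genes, which are not independent replicates, the correlation of the changes was r = 0.258 and Spearman's rho was 0.265.

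**Figure D4:**
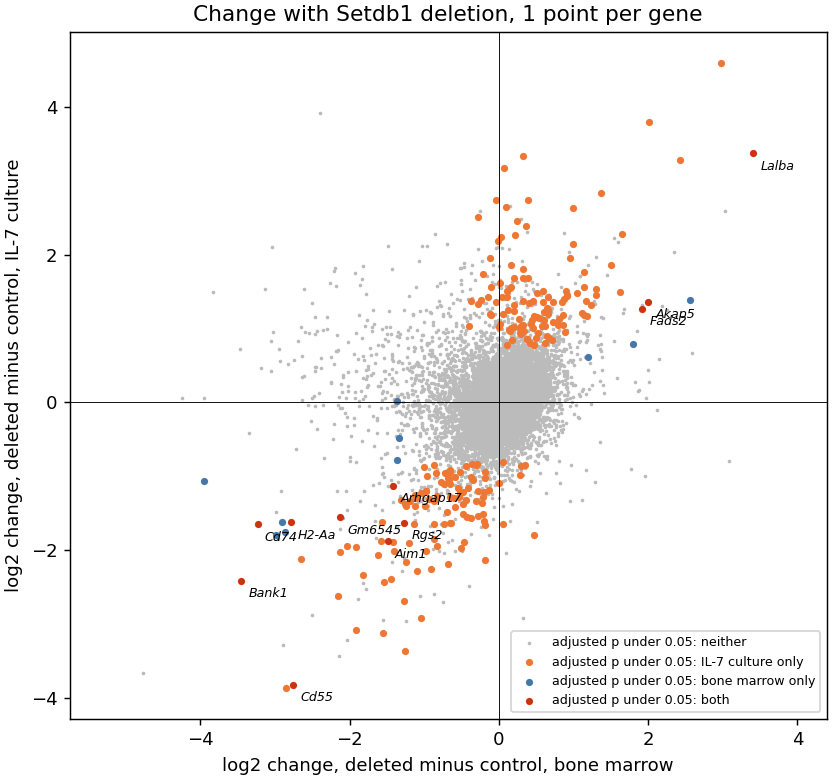
Log2 change with Setdb1 deletion in bone marrow (horizontal) against IL-7 culture (vertical), 1 point per gene, coloured by whether the adjusted p was under 0.05 in neither, 1 or both conditions. The 3 genes past in both at the upper right are Lalba, Akap5 and Fads2, and 8 lie at the lower left.

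The difference between the deletion effects in culture and in bone marrow was tested directly. With limma, 0 genes passed, the smallest adjusted p was 0.309, and 1216 genes (7.58%) had an unadjusted p under 0.05. With camera, 11 of 27 lists passed in this contrast, among them interferon response at a mean difference of 0.72 (adjusted p = 9.22e-06) and the unfolded protein response at 0.36 (adjusted p = 9.22e-06), and 0 passed with an estimated correlation (2 unadjusted) or in fry. The lists of pre-B and mature B genes, at a mean difference of 0.05 (adjusted p = 0.331), and cholesterol synthesis, at -0.12 (0.393), did not pass. Without bone marrow control 2 the count was 338 and without control culture 2 it was 3.

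Between cultured and bone marrow control cells, cholesterol synthesis genes rose by a mean of 1.22, with 8 of 16 past over all genes and 14 adjusted over the list alone, and Cyp51, a sterol demethylase, rose by 2.12 (SE 0.22, n = 2 per group, adjusted p = 0.0155). The camera adjusted p was 1.86e-20, the fry adjusted p was 0.00485, and the adjusted p with an estimated correlation was 0.135. Prg2, an eosinophil granule protein, fell by 5.08 (SE 0.56, adjusted p = 0.0186), and Mpo, the peroxidase of neutrophil granules, fell by 4.89 (SE 0.69, adjusted p = 0.0469). The bone marrow controls read Mpo at 9.60 and 11.19 and S100a8 at 12.31 and 12.46, so markers of other cells were high there. These falls, and all other falls of this contrast named below, were not told apart from a loss of RNA of other cells. Crhbp, which binds a stress hormone, rose by 4.42 (SE 0.30) and the growth factor Tgfb3 rose by 3.64 (SE 0.23).

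In this contrast 26 genes rose and 23 fell. Further rises were Myl10 (3.41, SE 0.32), Gpr177 (3.13, SE 0.22), Clgn (2.70, SE 0.27), Asns (2.69, SE 0.24), Bcar3 (2.36, SE 0.24), Stard7 (2.27, SE 0.14) and Pmepa1 (2.01, SE 0.21). Further falls were Tcfec (-3.61, SE 0.51), the elastase gene Ela2 (-3.56, SE 0.51), Abcd2 (-3.10, SE 0.26), the basophil protease Mcpt8 (-2.86, SE 0.31), Abca9 (-2.53, SE 0.31), Stom (-2.41, SE 0.31), the receptor Fcgr3 (-2.40, SE 0.33) and Tspan6 (-2.32, SE 0.28). The lower means of Tgfb3 (3.88), Abcd2 (3.47), Abca9 (4.02) and Tspan6 (3.88) lay under the value of 4.03 set for dim genes, so the sizes of their changes are uncertain, as for Tcfec (3.77 in control culture 1) and Mcpt8, which lay under it in control culture 2.

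Neutrophil and monocyte markers were lower in culture in 18 of 18 cases, by a mean of -2.99 (adjusted p = 1.42e-13, and 0.244 with an estimated correlation), with Mpo fallen over all genes and 11 fallen adjusted over the list alone. Mast cell and basophil markers had a mean of -1.45 (adjusted p = 1.37e-10, and 0.186 with an estimated correlation), with 2 of 9 fallen and 8 adjusted over the list alone. IL-7 and STAT5 targets had a mean of 0.48 (adjusted p = 0.000129, and 0.135 with an estimated correlation), with Socs2 risen by 1.84 (SE 0.22) and 4 risen adjusted over the list alone. Means of 0.74 for pre-B and mature B genes (adjusted p = 3.45e-06, and 0.365 with an estimated correlation) and 0.45 for p53 targets (1.32e-05, and 0.135 with an estimated correlation) stood beside 0 members past over all genes in limma (9 and 9 unadjusted), with 2 and 5 risen adjusted over the list alone. NK and innate lymphoid markers had a mean of -0.48 (adjusted p = 0.0676) and passed in camera with no filter (-0.45, adjusted p = 0.0051), with the mean of probesets (adjusted p = 0.0235) and without both culture arrays numbered 2 (-0.64, adjusted p = 0.0229). They also passed in 5 of the fits without 1 array, at an adjusted p from 0.0134 to 0.0417. Early B-lineage genes (0.19) and erythroid markers (-0.57) had the same adjusted p of 0.0676. In camera both passed with no filter (adjusted p = 0.0467 and 0.0282) and with the mean of probesets (0.0423 and 0.0219). Without bone marrow control 1 the early B-lineage mean was -0.09. Mitosis genes had a mean of -0.34 (adjusted p = 1.04e-07, and 0.33 with an estimated correlation) and immediate early and heat shock genes -0.55 (adjusted p = 0.00275, and 0.33 with an estimated correlation), with 0 past over all genes in limma (10 and 8 unadjusted) and 0 and 3 fallen adjusted over the list alone.

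DNA replication genes (-0.20, adjusted p = 0.00242, and 0.608 with an estimated correlation), stem and progenitor markers (-0.54, adjusted p = 0.0174, and 0.365 with an estimated correlation) and stromal and endothelial markers (-0.59, adjusted p = 0.0482, and 0.316 with an estimated correlation) also passed, and each call ended in several other fits. Over all genes in limma 0, 1 and 0 of their members fell (3, 4 and 4 unadjusted), and 0, 4 and 0 fell adjusted over the list alone, where 1 stem and progenitor marker rose. Without control culture 1 their adjusted p was 0.238, 0.131 and 0.139, without bone marrow control 1 that of DNA replication was 0.0954, and without bone marrow control 2 those of the other two were 0.329 and 0.128, with means of -0.40 and -0.84. With the neutrophil and monocyte covariate the means were 0.11 (camera adjusted p = 0.415), 0.06 (adjusted p = 0.684) and -0.09 (adjusted p = 0.912). Within groups this covariate differed by 2.41 and 2.05 between culture arrays and by 0.15 between bone marrow controls. Its slope thus rests mostly on the culture arrays and is extended over the difference of -2.99 between controls. The covariate fit therefore cannot show whether myeloid RNA accounts for these calls. With a filter at the 50th percentile stromal and endothelial markers had a mean of -1.07 (adjusted p = 0.0777). The count of 49 genes in limma was 0 without deleted array 1 or 2 of bone marrow (1543 and 1568 at an unadjusted p under 0.05), 14 without bone marrow control 1, 763 without bone marrow control 2, 7 and 13 without control culture 1 and 2, and 14 without deleted culture 1 or 2.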

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

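The tests of lists in the difference between both deletion effects, the tests of probesets without a gene symbol and the tests of neutrophil and monocyte RNA below were chosen after the data were seen.

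For 11 of 27 lists the deletion effect differed between culture and bone marrow in camera at a preset correlation. With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05), and fry gave 0. Interferon response genes had a difference, culture minus bone marrow, of 0.72 (adjusted p = 9.22e-06, and adjusted p = 0.443 with an estimated correlation). Deleted culture 2 lay 0.69 above deleted culture 1 for these genes, and control culture 2 lay at -0.22 relative to control culture 1. The unfolded protein response had a difference of 0.36 (adjusted p = 9.22e-06, and adjusted p = 0.44 with an estimated correlation). Glycolysis and hypoxia genes differed by 0.38 (adjusted p = 0.000741, and 0.443 with an estimated correlation).

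Mast cell and basophil markers differed by 0.69 (adjusted p = 0.000664, and 0.443 with an estimated correlation) and dendritic markers by 0.65 (adjusted p = 0.00368, and 0.44 with an estimated correlation). T cell markers differed by 0.48 (adjusted p = 0.00519, and 0.44 with an estimated correlation) and stromal and endothelial markers by 0.70 (adjusted p = 0.0488, and 0.44 with an estimated correlation). DNA replication genes had a difference of -0.28 (adjusted p = 0.0015, and 0.568 with an estimated correlation) and mitosis genes -0.19 (adjusted p = 0.0326, and 0.621 with an estimated correlation). Early B-lineage genes had a difference of -0.41 (adjusted p = 0.00537, and 0.57 with an estimated correlation) and heterochromatin machinery -0.19 (adjusted p = 0.0317, and 0.443 with an estimated correlation). Bone marrow means that enter these differences depended on single arrays. That of mast cell and basophil markers was -0.76, and -0.27 without bone marrow control 2. That of early B-lineage genes ran from -0.19 to 0.36 over the fits without 1 array.

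The array holds 25004 probesets without a gene symbol in the annotation used here, of which 18041 were tested. Over both conditions 27 were higher and 22 lower in deleted cells, adjusted over these probesets alone. In culture 16 were higher and 10 lower, and in bone marrow 0 passed in limma, against 610 higher and 719 lower at an unadjusted p under 0.05. Over both conditions, probesets 10510222 (3.79, SE 0.21) and 10538897 (3.04, SE 0.19) had the lowest p among those higher. Among those lower, 10521680 (-3.15, SE 0.19) and 10521679 (-3.17, SE 0.20) had the lowest p. Each had an adjusted p of 0.00429 in limma. Probesets were not ranked by the size of change. These 4 were chosen after their values were seen.

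Neutrophil and monocyte transcripts were higher in the culture arrays numbered 2 than in those numbered 1, in control and deleted cells alike. The smaller of both mean differences was 2.05. Scaling between arrays, which would move other genes as well, is argued against as the cause, since among the other 26 lists the highest difference in either group was 0.69 (median 0.08, SD 0.25). RNA of myeloid cells in these cultures may be the source: 88.9% of the markers, 16 of 18, were higher in array 2 of both groups, just under the share set for that explanation, so it stays open. Per the labels' protocols, pro-B cells were purified by fluorescence-activated sorting. The bone marrow arrays nevertheless read S100a8 at 12.31 and 12.46 in controls and at 11.97 and 11.94 in deleted cells. Sorting therefore does not speak against RNA of such cells. The abundant granule genes Ngp (9.63 and 10.07 against 3.74 and 5.39) and Lcn2 (9.04 and 9.46 against 3.91 and 4.42) were among the markers higher in array 2. The labels name no group that separates these arrays, so no biological explanation other than such cells was tested.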

How the results depend on the processing

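The covariate of neutrophil and monocyte markers and the fits without both culture arrays numbered 2 were alternatives chosen after seeing the data. With 2 arrays per group, the number of arrays limits the precision, and a fit without 1 array assumes that the lone array of its group varies like the other groups. Of 73 called values of named genes, 0 changed sign in the limma fits tried, and 684 of 1371 recomputations ended the call. In every called gene the arrays of 1 group all lay above those of the other. A fit without 1 array could therefore hardly turn a sign, and the count of 0 says little. The fits without deleted array 1 or 2 of bone marrow kept 1 of 73 each, and testing each probeset on its own also kept 1. Cd55 in culture was the 1 value that kept its call in every fit without 1 array. Scaling by quantiles kept 70 calls and by medians 72, and neither moved the median of all genes by over 0.1. The deposited values were already quantile normalised, and a further pass moved probesets by a median of only 0.018, so scaling was hardly tested here. Fits without 1 array have fewer samples and single probesets bring more tests. Fewer samples alone do not account for this, as leaving out bone marrow control 2 raised the counts in bone marrow and between controls. The difference between replicates had an SD of 0.541 in bone marrow controls, 0.256 in deleted bone marrow cells, and 0.394 and 0.422 in control and deleted culture. All contrasts share 1 estimate of each gene's spread, so calls in culture also rest on the bone marrow pairs. Beyond this the cause was not tested.

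The count of 21 genes in bone marrow was 36 with the mean of probesets, 37 with trend and robust variance, 49 with array weights, 86 at an adjusted p under 0.1, 0 with each probeset on its own (13376 unadjusted) and 0 with only the groups compared (1883 unadjusted). The 232 genes in culture became 121 with bright probesets, 454 at an adjusted p under 0.1, 0 with each probeset (18013 unadjusted), 104 with the covariate and 5 without both culture arrays numbered 2. The 459 genes over both conditions became 126 with each probeset, 907 at an adjusted p under 0.1 and 23 without both culture arrays numbered 2. The 49 genes between controls became 1 with each probeset, 118 at an adjusted p under 0.1, 8 with the covariate and 0 with only the groups compared (1559 unadjusted). Leaving out 1 array gave 0 to 531 genes in bone marrow, 1 to 287 in culture, 0 to 338 for the difference of both effects, 13 to 616 over both conditions and 0 to 763 between controls. In every other alternative with limma the difference of both effects gave 0 genes, from 939 to 1422 unadjusted over genes and 11585 over probesets.

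Of 28 list calls, camera with an estimated correlation kept 0 (at an unadjusted p under 0.05, 2 in bone marrow, 4 in culture and 5 between controls). The test fry called 7 lists, with 0 in bone marrow (8 unadjusted), 2 in culture and 5 between controls, among them NK markers (adjusted p = 0.0261 against 0.0676 in camera), and with the covariate camera called 5 between controls. With the covariate the adjusted p between controls was 0.0592 for p53 targets (0.30), 0.0812 for pre-B and mature B genes (0.49), and 0.171 for mitosis (-0.14, from -0.34) and for immediate early genes (-0.46, from -0.55). The call of DNA replication genes there ended and turned to 0.11 (adjusted p = 0.415). Glycolysis and hypoxia genes (0.38, adjusted p = 0.00159) and germline genes (-0.39, adjusted p = 0.0199) gained a camera call between controls with the covariate. Between controls the covariate fit extends a slope set mostly by the culture arrays, so it cannot show whether myeloid RNA accounts for calls lost or gained.

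The replicate numbers pair no samples by the labels, so a fit with them as a block says little about pairing. Deviations of arrays with the same number correlated at 0.0547 in bone marrow, 0.337 in culture and -0.122 between the controls. The replicate block gave 7 genes in bone marrow, 115 in culture, 28 between controls and 318 over both conditions. In camera, dendritic markers in culture (adjusted p = 0.0439) and erythroid markers between controls (-0.57, adjusted p = 0.0451) passed with it.

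The direction of 88 values turned, 82 of them shifts of lists not called and 5 the change of Setdb1, and 2 were past the threshold in either fit. Those were DNA replication above and interferon genes in culture, at -0.22 (adjusted p = 0.0326) without both culture arrays numbered 2. The direction is that of the test, so some values keep the sign of the mean. In bone marrow, T cell markers turned at 0.087 with no filter, 0.16 with a filter at the 50th percentile, 0.087 in fry and 0.12 with the covariate. Plasma cell markers turned at -0.13 with no filter, 0.10 at the 50th percentile and -0.13 in fry, and imprinted genes at 0.0070 in fry. In culture, the filter at the 50th percentile turned imprinted genes to 0.32, viral sensing to -0.030 and the BCL2 family to -0.0087, and fry turned IL-7 and STAT5 targets at 0.0086. The mean of probesets turned protocadherins to -0.080 and mast cell markers to 0.091, and the covariate turned imprinted genes at 0.054. Without both culture arrays numbered 2, heterochromatin machinery was at -0.053, imprinted genes at 0.072, viral sensing at -0.097 and IL-7 and STAT5 targets at 0.018.

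Between controls, no filter turned protocadherins at -0.0064, and the 50th percentile turned T cell markers at -0.11 and megakaryocyte markers at 0.11. The mean of probesets turned T cell markers at -0.074. The covariate turned imprinted genes at 0.015, interferon genes at 0.13, the BCL2 family at -0.0068, early B-lineage genes at 0.036 and dendritic markers at 0.50. Without both culture arrays numbered 2, germline genes were at -0.035, interferon genes at -0.020, glycolysis at -0.053, T cell markers at -0.19 and megakaryocyte markers at -0.19. Setdb1 over both conditions was at 0.0095 with bright probesets, and from -0.11 to 0.10 without 1 array.

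Leaving out 1 array in bone marrow gave -0.048 to 0.052 for imprinted genes, -0.19 to 0.36 for early B-lineage genes, -0.042 to 0.21 for T cell, -0.25 to -0.0084 for NK, -0.21 to -0.026 for megakaryocyte and -0.30 to 0.094 for plasma cell markers. In culture it gave -0.057 to 0.12 for heterochromatin machinery, 0.026 to 0.082 for imprinted genes, -0.025 to 0.17 for protocadherins, -0.087 to 0.59 for interferon genes, -0.086 to 0.025 for viral sensing, 0.0041 to 0.029 for IL-7 and STAT5 targets, -0.010 to 0.23 for mitosis, -0.44 to 1.98 for neutrophil and -0.24 to 0.13 for mast cell markers. Between controls it gave -0.29 to 0.031 for germline genes, -0.27 to 0.0095 for interferon genes, 0.065 to 0.20 for the unfolded protein response, 0.023 to 0.25 for the BCL2 family, -0.091 to 0.46 for early B-lineage genes, -0.043 to 0.13 for glycolysis, -0.20 to 0.10 for T cell, -0.43 to 0.23 for dendritic and -0.18 to 0.37 for megakaryocyte markers. For these turned values the cause was not tested.

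Fits with only the groups compared do not apply to the difference or the mean of both effects, which use all arrays. Lists with under 5 tested genes under an alternative gave no value there.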

Other observations

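The tests of the lower pre-B and mature B genes, the comparison within 4 classes of the size of change and the choice of genes named for uneven change along their probesets were made after the data were seen.

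Some genes passed a test for uneven change along their length. In limma's test of probeset usage within genes, 129 of 14647 genes passed in bone marrow, 274 in culture and 256 over both conditions. The test pools the spread over the probesets of a gene. It was not repeated without single arrays, and probesets that were dim in some arrays were not set apart. The calls below therefore rest on this test alone. Acoxl, a relative of the peroxisomal acyl-CoA oxidases, led over both conditions (adjusted p = 1e-09), with a gene-level change of 0.63 (adjusted p = 0.0956). Cd55 followed (adjusted p = 9.41e-07), beside its fall of the whole gene (-3.29). The transcription factor gene Tcf12 was next (adjusted p = 1e-06), with a gene-level change of -0.12 (adjusted p = 0.681). Samhd1, with a change of -1.59, was also past (adjusted p = 4.04e-05).

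Pre-B and mature B genes were lower in deleted cells of both conditions. Without bone marrow control 1 the mean change of the list in bone marrow was -2.06, but this array already had the lower mean, so that value decides nothing about RNA of other cells in it, which stays open in bone marrow. The list was lower in culture too, by a mean of -1.60, where no bone marrow array enters the difference. Mature B cells among the control cells may contribute and stay open. The labels' protocols name sorting of pro-B cells, but the bone marrow arrays read the neutrophil marker S100a8 at 11.94 to 12.46, so sorting does not settle this. Genes used mainly after the pro-B stage (Cr2, Fcer2a, Cxcr5, Ccr7 and Igh-5, the array's name for Ighd) had a median change of -1.39 (SD 1.12) and the rest of the list -1.72 (SD 1.12), a difference of 0.335 that lies within the spread. The rest of the list also holds genes used after the pro-B stage, such as Ms4a1 and Cd22. This comparison therefore cannot show whether mature B cells contributed. A direct or indirect effect of Setdb1 deletion, which the groups name, is also open and untested.

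The 459 genes changed over both conditions were set against the other ways of splitting the arrays within each condition. There are 18 splits, too few for a share under 0.05, and 1 gave as many genes, the real one, while the highest of the others gave 7. Most of the others put deleted and control arrays in 1 group, where any deletion effect adds to the spread and lowers the count. Another reverses the culture groups only, which gives the difference of both effects. The counts of the other splits therefore do not show how many genes chance alone would give.

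A hypothesis written before its result was seen held that rising genes carry transcripts that start or end inside the gene, so that more rising than falling genes would show uneven probeset usage. This was not found: 9.25% of rising genes (21 of 227) and 16.9% of falling genes (36 of 213) passed (two-sided Fisher's exact test p = 0.0225). Falling genes also changed more, as the median absolute log2 change of rising genes, 0.83, lay below theirs. Within 4 equal classes of the size of change the odds ratio, rising over falling, was 0.631 (95% interval 0.331 to 1.18, exact Mantel-Haenszel test p = 0.141), so the difference in size keeps this open.

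Another hypothesis, also written before its result was seen, held that changes extend over neighbouring genes, and rising genes may lie side by side more often than chance gives. Neighbours here are genes next to each other in the order of the 15970 tested genes that were placed on chromosomes. Genes not tested may lie between them, and distance was not used. Among genes that rose over both conditions 10 neighbouring pairs rose together, against a mean of 3.54 and an upper 95% bound of 7 in 100000 random draws (permutation p = 0.00282). The pairs included Fads3 with Fads2, Prkcq with Pfkfb3, St6galnac5 with St6galnac3, and Gm5111 with Repin1. Falling genes gave 16 pairs (permutation p = 1e-05, the smallest these draws can give), among them H2-Aa with H2-Ab1 and H2-Eb1, and Ms4a4a with Ms4a4c, so the pattern is not particular to rising genes. Families of related genes that lie together were not set apart in this test.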
